A study of Rattus norvegicus with 84 samples.

How the data were processed

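RNA-seq measured gene expression in rat embryos kept in whole embryo culture, in which conceptuses grow outside the mother in medium. Cultures were exposed for 4 h to TNP-470 at 0.25, 2.5 or 25 µM, to 5HPP-33 at 5, 15 or 30 µM, or served as control, per the labels. The submitters' design text gives culture medium as the control, and any vehicle in it is not stated. TNP-470 is a synthetic fumagillin analogue that binds methionine aminopeptidase MetAP2 and inhibits angiogenesis, and 5HPP-33 is a thalidomide analogue known to act on microtubules. The 84 libraries came from 56 single embryos (8 in each of 7 groups) and from 28 pools of visceral yolk sac (4 in each of 7 groups). Per the labels' protocols, tissue was kept in RNAlater, RNA went into a TruSeq kit, and reads of 50 bp were made in pairs on an Illumina instrument. What separates the embryos of a group beyond their title codes is not stated, so p-values measure the spread between these samples.

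The deposited values are expected counts per gene from RSEM, per the submitters' processing notes, which name the rat build rn5; the RSEM version, the aligner, the annotation release and any use of strand are not given in the sources used here. Expected counts divide reads that match several genes by estimated probability, so 34.5% of the values above 0 were not whole. Values of near-identical genes, such as ribosomal protein genes with their processed copies, globins and histone genes, are therefore uncertain, as are those of overlapping or antisense genes. The files listed 26405 Ensembl genes, of which 19796 carried a symbol and 6609 did not, and 447 symbols stood for more than 1 identifier. Genome positions were not used here. Total expected counts per library ran from 8.3e6 to 14.9e6 in embryos (median 11.0e6) and from 9.6e6 to 13.9e6 in yolk sacs (median 11.4e6). No library pair held identical values.

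Groups came from the labelled tissue, chemical and concentration. One title text, TNP_25, stands on libraries of both 0.25 and 25 µM, and the labelled concentration separated them. Titles also carry a code, 523 or 524, of unstated meaning, which divides every group evenly, a title number and, for embryos, a letter A or B. Libraries are named by the start of their titles, such as Control_524_1B. A lane number was read from each file's name, on the assumption that it names the sequencing lane. Lanes were not balanced over groups. Control embryos of code 523 lay in lane 1, with 1 in lane 6, whereas the code 523 embryos of 25 µM TNP-470, 5 µM 5HPP-33 and 15 µM 5HPP-33 all lay in lane 2.

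Expected counts were rounded to whole numbers. Genes were kept by filterByExpr over the groups, which left 13976 genes in embryos, 13480 in yolk sacs and 14881 over both tissues. Counts were scaled by TMM factors and tested with the edgeR quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), with all groups of a tissue in the fit and the title code as covariate. Adjusted p is the Benjamini-Hochberg value over all genes tested, and a gene was called at an adjusted p under 0.05. Each dose was compared with its control. The ordered trend over control and 3 doses used weights of -3, -1, 1 and 3 and is given as log2 change per step of dose. TNP-470 at 25 µM was also compared with 5HPP-33 at 30 µM. A fit of all 84 libraries gave the difference between yolk sac and embryo responses at each top dose, and the difference between the tissues in control cultures. CPM values are scaled by the same factors, and log2 CPM used a prior count of 2.

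The 33 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 384 tests of 32 lists in each tissue and comparison. Camera compares a list with all other genes, and its call is not a call of any member. With a correlation estimated from the data, 4 of 108 calls held, those of the p53 target list in embryos at the 3 TNP-470 doses and at 30 µM 5HPP-33. Members called are counted over all genes tested and also adjusted over the list alone.

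The design, the gene lists, the listed alternatives and the rule for named genes were fixed before the data were examined. Named genes have a symbol and at least 5 CPM in a group. At the top doses they are the 8 called genes with the largest rise and the 8 with the largest fall, with every treated library on one side of the control mean. At other doses they are the 3 largest each way by the same rule, or all genes where 5 or fewer were called. In the trend, direct, tissue and response comparisons they are the 4 largest each way, without the condition on single libraries. Up to 4 members with the smallest p were added from each called list. Some genes that this rule names are not reported here. Cdkn1a, Mdm2, Ccng1, Metap1, Metap2, Crbn, Sall4, Kdr, Flt1, Tek, Cdh5, Vegfa, Ccnb1, Plk1, Tubb2b, Tubb5, Atf4, Hmox1, Cyp1a1, Afp and Sox2 were always eligible. Other members of called lists, and genes named to describe single libraries, were chosen after their values were seen.

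Simulated data with known changes tested the scripts. At the embryo comparison of 25 µM TNP-470, the test recovered 85.1, 95.5 and 97.0% of genes changed by 1.5, 2 and 4 fold. Of its calls among 13906 genes tested 3.9% were false. For the same yolk sac comparison it recovered 52.2, 83.6 and 100%, and 4.2% of its calls among 13397 genes tested were false. Alternatives planned were the DESeq2 Wald test (DESeq2 1.42.0), RLE factors, no filter on low counts, no title code, lane in place of the title code, the compared groups alone, each title code alone, embryos A and B of a title number summed, limma-voom with the title number as a random block, and leaving out yolk sac libraries in turn. Alternatives chosen after seeing the data were the slope of each library on gene length as a covariate, leaving out single embryos or libraries with unusual marker levels, embryo A or B alone, lanes that held both groups, and limma-voom sample quality weights. Splits of the samples, the real one included, numbered 40 for embryos, 35 or 40 for yolk sacs and 25 for fits over both tissues. Unchanged groups against the shared controls were simulated 20 times.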

Results

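Rat embryos in whole embryo culture met 2 compounds that interfere with vessel formation by different routes, namely TNP-470 and 5HPP-33. The question was which transcripts changed within 4 h in the embryo and in its visceral yolk sac. Libraries came from 8 single embryos and 4 yolk sac pools in each of 7 groups: medium, TNP-470 at 0.25, 2.5 or 25 µM, and 5HPP-33 at 5, 15 or 30 µM. Depth was 8.3e6 to 14.9e6 expected counts in embryos and 9.6e6 to 13.9e6 in yolk sacs. Each group divided evenly between title codes, here code-523 and code-524. Sequencing lanes followed the groups in part, so the tests were also run with lane as covariate. Fits within each title code were run too. Within a code, only embryos at 0.25 µM TNP-470, and those at 2.5 µM in code-523, shared a lane with control embryos. At the other doses a fit within a code cannot tell lane from compound in embryos.

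TNP-470 at 25 µM raised the transcripts of p53 targets in embryos. Cdkn1a (ENSRNOG00000000521), which encodes the cell cycle inhibitor p21, went from 5.62 ± 1.05 to 60.4 ± 6.09 CPM (mean ± SD, n = 8 embryos per group), a log2 fold change of 3.42 ± 0.13 (SE, adjusted p = 3.28e-28, edgeR quasi-likelihood). Ccng1 (ENSRNOG00000003256), cyclin G1, went from 40 ± 5.28 to 484 ± 58.5 CPM (3.60, adjusted p = 3.19e-27). The death receptor Fas (ENSRNOG00000019142) rose from 0.568 ± 0.240 to 7.46 ± 1.38 CPM (3.68) and Eda2r (ENSRNOG00000013018), a receptor of the same family, from 0.666 ± 0.345 to 11.7 ± 1.68 CPM (4.07). Phlda3, which restrains AKT, rose by 2.93 in log2, the nuclease gene Aen by 1.83 and Rps27l, a p53 target counted here among the ribosomal protein genes, by 0.87. Mdm2 (ENSRNOG00000006304), the ubiquitin ligase that limits p53, doubled from 65.9 ± 5.38 to 133 ± 7.98 CPM (1.02). Of the 28 p53 targets in the list, 16 rose and 2 fell (Ptp4a3 -0.47, Fdxr -0.23), and adjusted over the list alone the counts were the same. Camera gave the list an adjusted p = 6.46e-49 (adjusted p = 2.3e-10 with an estimated correlation). Lane as covariate gave 13 higher targets, with log2 fold changes of 3.49 for Cdkn1a, 3.54 for Ccng1 and 0.84 for Mdm2.

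Genes outside that list were among the largest rises. Svop (ENSRNOG00000000693), a synaptic vesicle protein gene, went from 0.237 ± 0.120 to 6.41 ± 1.85 CPM (log2 4.72). Alox5, which makes leukotrienes, rose by 3.64, the ion channel family gene Ano3 by 3.36, and Abcb1b, which encodes a drug efflux pump, by 3.31 from 1.65 ± 0.501 to 16.6 ± 3.17 CPM. By the rule that named these genes, each lay above the control mean in all 8 treated embryos. Methionine aminopeptidase itself, the protein TNP-470 binds, differed little: Metap2 rose from 268 ± 20.9 to 327 ± 20.3 CPM (0.28, adjusted p = 0.000279; 0.12 with lane as covariate). Metap1, its paralogue, rose by 0.10 (adjusted p = 0.0476), which was 0.05 with lane and no longer called without embryo Control_524_1B.

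Transcripts for amino acid supply fell at the same dose. The transporter genes Slc7a1 (70.2 ± 47.0 to 21.1 ± 4.12 CPM, log2 -1.73), Slc7a5 (-1.65), Slc1a4 (-1.45) and Slc6a9 (-1.76) fell. So did the glutathione-cleaving enzyme gene Chac1 (16.0 ± 16.9 to 1.55 ± 1.09 CPM, -3.34), the secreted stanniocalcin gene Stc2 (-2.68), Pycr1 of proline synthesis (-1.04) and Shmt2 of serine use (-0.73). These are targets of ATF4, whose own transcript fell by 0.33. Among the 24 ATF4 targets 15 fell and 0 rose, also when adjusted over the list alone (camera, adjusted p = 5.12e-06; adjusted p = 0.818 with an estimated correlation). Embryo Control_524_1B held the highest levels of this group among the controls. Without it 10 targets were lower and the mean log2 fold change of the list was -0.613 in place of -0.913. Slc7a3, another amino acid transporter gene, went from -1.29 to -0.58 and was no longer called without that embryo. No member was called with lane as covariate. Values were then -0.71 for Slc7a1, -0.69 for Slc7a5, -0.78 for Slc1a4, -0.47 for Slc6a9, -1.01 for Chac1, -0.72 for Stc2 and -0.08 for Atf4. Celsr1, a planar polarity cadherin gene, fell from 23.7 ± 8.00 to 9.86 ± 1.76 CPM (-1.27; -0.57 with lane).

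Genes of the vessel wall were lower by a smaller amount. The VEGF receptor genes Kdr (87.4 ± 13.6 to 62.4 ± 5.98 CPM, log2 -0.49, adjusted p = 0.00412) and Flt1 (-0.57) fell. So did Flt4 (-0.61), the endothelial cadherin gene Cdh5 (-0.46), Plvap (-0.65), Notch4 (-0.50) and Nos3 (-0.49), while Egfl7 (0.21) and Emcn (0.33) rose. Tek, which encodes an angiopoietin receptor, did not pass the test (0.06, adjusted p = 0.722). Of 29 endothelial markers 13 fell and 2 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.013; adjusted p = 0.866 with an estimated correlation). No marker was called with lane as covariate, where Kdr was -0.18, Flt1 -0.32 and Cdh5 -0.21. The ligand gene Vegfa fell by 0.41, which was -0.29 and not called without embryo Control_524_1B, and -0.25 with lane. The angiogenic signalling list was not called (camera, adjusted p = 0.611), with 8 of 27 members lower, such as Nrp2 (-0.66) and Ephb4 (-0.49), and 4 higher, such as Mmp2 (0.62).

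Other groups at 25 µM changed by small amounts in many members. Ribosomal protein genes rose in 69 of 111 members and fell in 2 (76 and 3 adjusted over the list alone; Rps19 0.34, Rpl19 0.35), with adjusted p = 1.81e-09 by camera and adjusted p = 0.866 with an estimated correlation. All 13 mitochondrially encoded genes rose (also over the list alone), ND2 by 0.58, with adjusted p = 1.16e-06 and adjusted p = 0.661 with an estimated correlation. Mitosis genes rose in 20 of 28 members (22 over the list alone; Cenpe 0.40, Mki67 0.35, Ccnb2 0.31, Ccnb1 0.23) and fell in 2, Plk1 (-0.38) and Cdc20 (-0.30), with adjusted p = 9.1e-06 and adjusted p = 0.616 with an estimated correlation. Hypoxia response genes fell in 10 of 25 members by either adjustment, such as the glycolysis genes Hk2 (-0.77) and Aldoa (-0.63) (adjusted p = 0.00527; adjusted p = 0.866 with an estimated correlation). Histone genes rose in 7 of 22 members by either adjustment (adjusted p = 0.0333; adjusted p = 0.866 with an estimated correlation). With lane as covariate 1 ribosomal protein gene and 2 histone genes were called and none of the mitochondrial, mitosis or hypoxia members was. ND2 was then 0.24, Ccnb1 0.14, Plk1 -0.02, Hk2 -0.53 and Aldoa -0.34. Each library's slope on gene length also differed, from 0.037 ± 0.024 in controls to -0.034 ± 0.020 at this dose. With that slope as covariate 2 ribosomal protein genes rose and 5 fell, and 1 mitochondrially encoded, 5 mitosis and 1 histone gene rose. Hypoxia genes were lower in 4 members, and no ATF4 target or endothelial marker was called. The mean of the ribosomal protein list went from 0.236 to 0.008 and that of the ATF4 list from -0.913 to -0.469.

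Chaperone genes of the endoplasmic reticulum fell in 7 of 20 members by either adjustment, led by Herpud1 (-1.19; -0.50 with lane) and Hyou1 (-0.52), with adjusted p = 0.0313 and adjusted p = 0.866 with an estimated correlation. That list was no longer called when 15 embryos with unusual heart or yolk sac endoderm markers were left out. WNT targets fell in 4 of 18 members by either adjustment, such as Lef1 (-0.60; -0.20 with lane), with adjusted p = 0.022 and adjusted p = 0.866 with an estimated correlation. Nkd1, another member, was -0.40 in the main fit and 0.04 with lane. The calls of Nkd1 and of the list were lost without embryo Control_524_1B. Sall4, a limb transcription factor gene tied to thalidomide, fell from 94.1 ± 16.9 to 54.4 ± 7.48 CPM (-0.79; -0.32 with lane). The thalidomide receptor gene Crbn rose by 0.27 (0.18 with lane), and the tubulin gene Tubb5 fell by 0.46 (-0.15 with lane). Hmox1 of haem breakdown went from 14.3 ± 4.01 to 30.8 ± 29.5 CPM (0.96; 0.35 with lane; 0.86 and not called without embryo Control_524_1B). Cyp1a1 (-0.56, adjusted p = 0.0536), Sox2 (-0.39, adjusted p = 0.0831) and Afp (0.89) did not pass. Lists not called at this dose were the heart muscle (adjusted p = 0.616), retinoic acid (0.317), cereblon and limb (0.199), aryl hydrocarbon receptor (0.422), interferon (0.703) and methionine aminopeptidase (0.326) lists.

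At 25 µM 5267 of 13976 genes were called, 2689 higher and 2578 lower. Treated embryos of this dose shared no lane with controls, so the lane fit links them only through other groups. Within code-523 4200 genes were called, within code-524 946, and with lane as covariate 103, of which 99 were higher. The median SE over genes was 0.155 with lane in place of 0.102. For the genes called in the main fit the median absolute log2 fold change was 0.157 with lane in place of 0.312.

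The p53 response to TNP-470 was already near its full size at the lowest dose. At 0.25 µM Cdkn1a rose to 56.5 ± 10.5 CPM (log2 3.32, adjusted p = 1.72e-27) and Ccng1 to 360 ± 103 CPM (3.17), and at 2.5 µM they reached 63.5 ± 7.12 CPM (3.49) and 473 ± 38.5 CPM (3.56), with n = 8 embryos each. Svop rose by 4.78 and 4.69, Alox5 by 3.56 and 3.60, Eda2r by 3.55 and 4.00, Phlda3 by 2.84 and 2.95 and Aen by 1.74 and 1.85 at the 2 doses. Mdm2 rose by 0.68 and 0.89. The mean log2 fold change of the p53 targets was 0.94 at 0.25 µM, 1.02 at 2.5 µM and 1.0 at 25 µM. At 0.25 µM 15 of 28 targets rose and 0 fell by either adjustment (camera, adjusted p = 7.02e-114, and adjusted p = 5.31e-16 with an estimated correlation). At 2.5 µM 16 rose and 2 fell, or 16 and 3 adjusted over the list alone (camera, adjusted p = 1.54e-67, and adjusted p = 2.14e-12 with an estimated correlation). At each dose 15 were called higher with lane as covariate too.

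**Figure D1:**
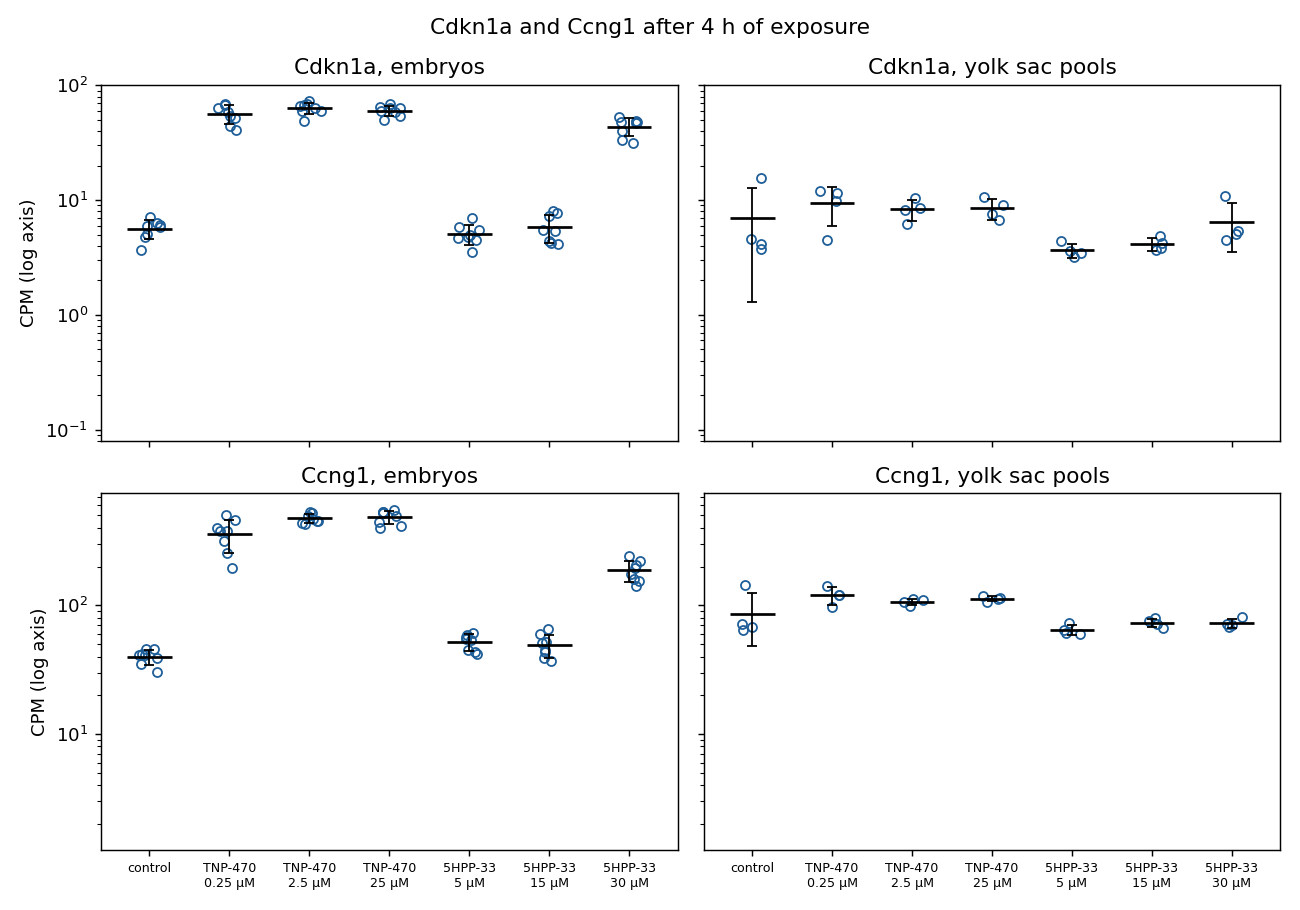
Expression of Cdkn1a and Ccng1 in embryos (n = 8 per group) and yolk sac pools (n = 4 per group), in CPM on a log axis; circles are libraries, lines means and bars SD. In embryos Cdkn1a stood at 5.62 CPM in controls, above 56 CPM at all TNP-470 doses and at 43.8 CPM at 30 µM 5HPP-33, while it was at 3.22 to 12.1 CPM in treated yolk sac pools and at 3.78 to 15.7 CPM in yolk sac controls, the highest of them pool Control_524_1. Ccng1 was at 63.8 to 71 CPM in the other 3 control pools and at 96.3 CPM or more in all 12 TNP-470 pools.

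Apoptosis genes that p53 controls rose as well at 0.25 µM. Bax, which opens the mitochondrial membrane, went from 84.2 ± 3.26 to 125 ± 10.6 CPM (log2 0.57) and Bbc3, which encodes PUMA, rose by 0.80. Of 18 genes of the BCL2 and caspase list, which shares Bax and Bbc3 with the p53 list, 3 rose, or 3 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.00618; adjusted p = 0.088 with an estimated correlation).

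Amino acid genes were lower from the lowest dose in the main fit. Chac1 fell by 3.23 at 0.25 µM and by 3.10 at 2.5 µM, Slc7a1 by 1.31 and 1.42, and Slc6a9 by 1.58 and 1.79. The ATF4 list had 4 of 24 members lower at 0.25 µM, or 13 over the list alone (camera, adjusted p = 2.43e-09; adjusted p = 0.691 with an estimated correlation), and 16 at 2.5 µM, or 17 over the list alone (camera, adjusted p = 6.89e-07; adjusted p = 0.772 with an estimated correlation). Embryo Control_524_1B carried much of this. Without it 0 members were lower at 0.25 µM and 5 at 2.5 µM. The mean log2 fold change of the list went from -0.737 to -0.431 and from -0.860 to -0.562. At 0.25 µM the calls of Chac1 (-2.61), Slc6a9 (-1.14), Slc7a1 (-0.98), Mthfd2 (-0.63 to -0.42) and Psat1 (-0.58 to -0.38) were lost without that embryo. At 2.5 µM those of Stc2 (-2.57 to -1.89), Atf4 (-0.27 to -0.20) and Vegfa (-0.43 to -0.31) were lost. Lane as covariate left 2 members called at 0.25 µM and 0 at 2.5 µM, where Chac1 was -2.10, Stc2 -1.13, Slc6a9 -1.04 and Slc7a5 -0.97 (-1.49 in the main fit).

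At 0.25 µM mitosis genes rose in 3 of 28 members (6 over the list alone; Aurka 0.23, Prc1 0.18, Ube2c 0.18, the last not called at 0.15 without embryo Control_524_1B), with adjusted p = 0.000208 by camera and adjusted p = 0.727 with an estimated correlation. Ribosome biogenesis genes rose in 1 of 25 (5 over the list alone; Nop58 0.20, not called at 0.19 without embryo Control_524_1B), with adjusted p = 0.000745 and adjusted p = 0.77 with an estimated correlation. The ribosomal protein list shifted upward (adjusted p = 8.99e-05; adjusted p = 0.915 with an estimated correlation), although Rps27l alone rose (0.69) and 3 of 111 genes fell, such as Rpl3 (-0.28) and Rpl10a (-0.28), with 2 and 3 over the list alone. Chaperone genes of the endoplasmic reticulum fell in 2 of 20 (3 over the list alone; Herpud1 -0.94, Sdf2l1 -0.48), with adjusted p = 0.00239 and adjusted p = 0.818 with an estimated correlation. The mitochondrially encoded (adjusted p = 0.00634; adjusted p = 0.866 with an estimated correlation) and histone lists (adjusted p = 0.0494; adjusted p = 0.866 with an estimated correlation) shifted upward without a called member.

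At 2.5 µM mitosis genes rose in 18 of 28 members (20 over the list alone; Kif23 0.22), with adjusted p = 4.75e-06 by camera, adjusted p = 0.596 with an estimated correlation and 4 members with lane. Cholesterol synthesis genes fell, such as Srebf2 (-0.46), in 6 of 21 members or 7 over the list alone (adjusted p = 0.00423; adjusted p = 0.866 with an estimated correlation). Herpud1 (-1.17) and Sdf2l1 (-0.72) led 7 of 20 lower chaperone genes of the endoplasmic reticulum, or 8 over the list alone (adjusted p = 0.000524; adjusted p = 0.764 with an estimated correlation). Ribosome biogenesis genes rose in 11 of 25 members, such as Noc3l (0.38), or 13 over the list alone (adjusted p = 0.000846; adjusted p = 0.77 with an estimated correlation). Heat shock genes rose in 4 of 15 by either adjustment, with Chordc1 at 0.39 and Hsp90aa1 at 0.34 (adjusted p = 0.034; adjusted p = 0.727 with an estimated correlation). Without embryo Control_524_1B 2 members and not the list were called. Ribosomal protein (27 of 111 higher, 39 over the list alone, adjusted p = 4.75e-06, adjusted p = 0.866 with an estimated correlation) and mitochondrially encoded genes (7 of 13, 12 over the list alone, adjusted p = 0.000202, adjusted p = 0.799 with an estimated correlation) shifted upward. With the slope on gene length as covariate their means went from 0.146 to 0.007 and from 0.296 to 0.136, as that of the ribosomal protein list at 0.25 µM went from 0.117 to -0.015. Hypoxia genes shifted downward (7 of 25, 8 over the list alone, adjusted p = 0.0233, adjusted p = 0.866 with an estimated correlation), as did visceral endoderm genes (1 of 27, 0 over the list alone, adjusted p = 0.00507, adjusted p = 0.927 with an estimated correlation). Metap2 rose by 0.27 (0.21 with lane), and Cyp1a1 fell from 6.19 ± 2.86 to 3.20 ± 0.447 CPM (-0.93).

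Across control and the 3 TNP-470 doses the largest rises per step of dose were Svop (1.41), Eda2r (1.27), Fas (1.12) and Ccng1 (1.12), and the largest falls were Chac1 (-0.99), Stc2 (-0.89), Slc6a9 (-0.55) and the splicing factor gene WBP11 (-0.54). With lane as covariate the rises were 1.42, 1.19, 1.07 and 1.11 and the falls -0.19, -0.16, -0.10 and -0.24. Each value is the slope of a line over dose ranks and does not show a change at every step. Ccng1 was 3.17, 3.56 and 3.60 against control at 0.25, 2.5 and 25 µM, so most of its rise was present at 0.25 µM. In the main fit 332 genes were called at 0.25 µM, 257 of them higher. At 2.5 µM 3163 were called, 1734 of them higher, and in the trend 5702. Within code-523 and code-524 the counts were 115 and 75 at 0.25 µM and 1842 and 236 at 2.5 µM. Lane as covariate gave 288 at 0.25 µM, 468 at 2.5 µM and 99 in the trend.

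5HPP-33 at 30 µM also raised p53 targets in embryos. Cdkn1a went from 5.62 ± 1.05 to 43.8 ± 7.84 CPM (log2 2.96, adjusted p = 1.16e-24, n = 8 per group) and Ccng1 from 40 ± 5.28 to 187 ± 35.0 CPM (2.22, adjusted p = 3.1e-18). Phlda3 rose by 2.39, Aen by 0.89, Mdm2 by 0.65 and Bbc3 by 0.99. Tap1, which carries peptides for antigen presentation, rose from 0.590 ± 0.233 to 5.70 ± 1.35 CPM (3.25), the phosphatase gene Ptprv from 1.26 ± 0.777 to 10.7 ± 2.56 CPM (3.07), Alox5 by 3.58, Abcb1b by 2.70 and Prrg4 by 1.96. The mean log2 fold change over the 28 p53 targets was 0.74. Among them 16 rose and 0 fell, or 16 and 1 when adjusted over the list alone (camera, adjusted p = 6.37e-56, and adjusted p = 4.65e-11 with an estimated correlation). Lane as covariate gave 15 higher targets, and Cdkn1a was 2.95 and Ccng1 2.28. Of the BCL2 and caspase list Bbc3, Bax (0.25) and Apaf1 (0.22) rose and Casp2 fell by 0.17 (-0.16 and not called without embryo Control_524_1B), with 4 higher and 1 lower over the list alone (adjusted p = 0.034; adjusted p = 0.317 with an estimated correlation). That list lost its call when the 15 embryos with unusual markers were left out.

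DNA replication genes fell. Cdc45 (-0.27), Mcm6 (-0.25), Mcm4 (-0.22) and Mcm2 (-0.21), parts of the replicative helicase, were among 5 of 25 lower members, or 8 adjusted over the list alone (camera, adjusted p = 2.11e-06; adjusted p = 0.418 with an estimated correlation), and 3 members were lower with lane as covariate. Actin cytoskeleton genes driven by SRF and YAP rose: Tpm1 from 426 ± 62.8 to 637 ± 218 CPM (0.57), Cnn2 by 0.44, and Vcl (0.32) and Actg1 (0.28), which without embryo Control_524_1B were 0.28 and 0.26 and not called. In that list 5 of 21 members rose, or 10 over the list alone (camera, adjusted p = 5.21e-06; adjusted p = 0.596 with an estimated correlation), and 6 with lane. Immediate early genes rose in 5 of 20 members, 7 over the list alone, such as Btg2 (0.81), Fosl1 (0.75), Junb (0.58) and Zfp36 (0.55; 0.53 and not called without embryo Control_524_1B), with adjusted p = 0.0476 and adjusted p = 0.764 with an estimated correlation. Tubulin genes, whose protein the compound acts on, differed little. Tubb2b fell by 0.23 (-0.22 and not called without embryo Control_524_1B), and Tubb5 did not pass (-0.17, adjusted p = 0.281).

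Genes of the nervous system and somites were lower at 30 µM. Hes5 (-1.05), Olig2 (-0.98), Neurog2 (-0.92) and Pax6 (55.8 ± 3.97 to 32.4 ± 15.9 CPM, -0.79), all regulators of neural progenitors, fell. The calls of Olig2 (-1.02) and Neurog2 (-0.92) were lost without embryo Control_524_1B. That list had 4 of 20 members lower, or 5 over the list alone (camera, adjusted p = 3.92e-06; adjusted p = 0.691 with an estimated correlation). Embryos HPP_30_523_14A, HPP_30_523_14B and HPP_30_524_14B held the lowest levels of this group. Without the 15 embryos with unusual heart or yolk sac endoderm markers, which include these 3, no member was called and the list mean went from -0.420 to -0.049. Somite genes, such as Meox2 (10.7 ± 1.42 to 5.76 ± 3.37 CPM, -0.88) and Lfng (-0.46), fell in 2 of 18 members, or 5 over the list alone (adjusted p = 3.47e-06; adjusted p = 0.596 with an estimated correlation), and without those embryos the list mean was -0.264. With embryo HPP_30_524_14A left out as well, which left 3 treated embryos, that mean was -0.048 (camera, unadjusted p = 0.225). Leaving out that embryo alone gave a list mean of -0.236 with 3 members lower (camera, unadjusted p = 2.67e-05). The tight junction gene Cldn1 fell by 0.93, Ssc5d by 0.84, Col7a1 by 0.71, Tagln3 by 0.64 and the nicotinic receptor gene Chrna7 by 0.67.

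Stress responses at 30 µM were modest. Chaperone genes of the endoplasmic reticulum rose, opposite to TNP-470: Hyou1 by 0.36, Dnajc3 by 0.35 and Dnajb11 by 0.31, none of them called without embryo Control_524_1B (0.30, 0.29 and 0.24). That list had 3 of 20 members higher, or 13 over the list alone (camera, adjusted p = 3.36e-06; adjusted p = 0.596 with an estimated correlation). Osgin1 (0.227 ± 0.164 to 1.78 ± 2.35 CPM, 2.84) and Gclm (0.55; 0.48 and not called without embryo Control_524_1B), targets of NRF2, were the 2 higher members of 18, or 7 over the list alone (adjusted p = 0.0062; adjusted p = 0.661 with an estimated correlation). Mitochondrially encoded genes rose in 4 of 13 members, or 10 over the list alone (adjusted p = 7.02e-06; adjusted p = 0.727 with an estimated correlation). Without embryo Control_524_1B ND3 (0.37), ND5 (0.36) and ND6 (0.41) lost their calls. Visceral endoderm genes shifted upward with 0 members called, or 4 over the list alone (adjusted p = 0.0011; adjusted p = 0.907 with an estimated correlation), and so did erythroid genes (adjusted p = 0.0059; adjusted p = 0.891 with an estimated correlation). Embryo HPP_30_524_13A stood highest in yolk sac endoderm markers. Without the 15 embryos with unusual markers the NRF2, mitochondrial, erythroid and visceral endoderm lists were not called. Their means went from 0.446 to 0.102, 0.290 to 0.050, 0.399 to -0.165 and 1.411 to 0.244. Those embryos were chosen by visceral endoderm or heart markers, so the loss of the visceral endoderm shift followed from that choice. They include HPP_30_523_14A, HPP_30_523_14B, HPP_30_524_13A and HPP_30_524_14B, so fewer treated embryos were left to test the other lists. The ATF4 list shifted downward (adjusted p = 0.00117; adjusted p = 0.866 with an estimated correlation) and was not called without embryo Control_524_1B.

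Cyp1a1, the drug-metabolising target of the aryl hydrocarbon receptor, fell from 6.19 ± 2.86 to 2.23 ± 1.32 CPM at 30 µM (-1.44, adjusted p = 0.000282; -1.37 with lane). The endothelial genes Kdr (-0.03), Flt1 (-0.07), Cdh5 (0.01) and Tek (0.05), and Vegfa (-0.26, adjusted p = 0.283), Crbn (-0.02, adjusted p = 0.902), Sall4 (0.07, adjusted p = 0.851), Metap2 (-0.04) and Afp (1.72), did not pass. The angiogenic signalling (camera, adjusted p = 0.799), retinoic acid (0.234), heart muscle (0.556), cereblon and limb (0.941) and interferon (0.5) lists were not called. In all 789 genes were called, 474 higher and 315 lower. The count was 80 in a fit of code-523 alone, 298 in a fit of code-524 alone and 317 with lane as covariate. Without embryo Control_524_1B 516 genes were called. Without the 15 embryos with unusual markers, a fit that held fewer treated embryos, 97 were. Fewer of the lower calls stayed in some of these fits, with 13 lower in code-523, 9 without the 15 embryos and 0 of 29 in the lane holding both groups. In that lane, lane 3, treated embryos were all of code-523 and controls all of code-524.

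At 5 µM 5HPP-33 p53 targets did not respond as a group, and developmental and blood genes differed from control. Cdkn1a was at 5.10 ± 1.03 CPM against 5.62 ± 1.05 in controls (-0.14), Ccng1 rose by 0.37 and Mdm2 by 0.26 (0.31 and 0.07 with lane), and the p53 list was not called (camera, adjusted p = 0.889), with 2 of 28 members higher and 4 lower, or 1 and 2 over the list alone. Erythroid genes rose in 17 of 27 members, or 21 over the list alone, among them Hbe2 (1.67), HBB (3.95 ± 1.6 to 11.3 ± 5.15 CPM, 1.51), the globin chaperone gene Ahsp (1.3) and the transferrin receptor gene Tfrc (0.43). Camera gave the list an adjusted p = 7.21e-07 (adjusted p = 0.764 with an estimated correlation). Without the 15 embryos with unusual markers, of which 3 belong to this group, 4 erythroid genes were higher and the list mean went from 0.826 to 0.350. Neural progenitor genes fell in 9 of 20 members by either adjustment, among them En1 (-1.65) and Sox2 (-0.73), with adjusted p = 0.0011 and adjusted p = 0.866 with an estimated correlation, and 6 were lower without those embryos. Neural crest genes such as Dlx2 (-0.94), Sox9 (-0.76) and Twist1 (-0.50) fell in 10 of 16 members, or 12 over the list alone (adjusted p = 0.00178; adjusted p = 0.661 with an estimated correlation). HBB was 1.78 and Sox2 -0.60 with lane as covariate, without a call.

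Ribosomal protein genes rose in 82 of 111 members at 5 µM (88 over the list alone; Rps26 0.37) and fell in 1 (camera, adjusted p = 1.56e-15; adjusted p = 0.764 with an estimated correlation). Mitochondrially encoded genes rose in 11 of 13 by either adjustment, COX1 by 0.45 (adjusted p = 3.36e-06; adjusted p = 0.691 with an estimated correlation). Mitosis genes rose in 16 of 28, such as Cdk1 (0.28), and fell in 2, Plk1 (-0.49) and Cdc20 (-0.45), or in 3 over the list alone (adjusted p = 0.000984; adjusted p = 0.77 with an estimated correlation). The ATF4 list had 7 of 24 lower by either adjustment (adjusted p = 0.0111; adjusted p = 0.921 with an estimated correlation), and without embryo Control_524_1B it was not called. Slc7a1 (-1.05, and -0.71 without that embryo) and Stc2 (-1.65 and -0.99) lost their calls too, and Stc2 was 0.30 with lane. Zfp711 rose by 1.02 and the melanocyte transporter gene Oca2 by 0.97, and WBP11 (-1.55), Slc7a5 (-1.43; -0.47 with lane), Sall4 (-0.70; -0.23 with lane) and Tubb5 (-0.44; -0.12 with lane) fell. No member of the lists called at this dose was called with lane as covariate, nor with each library's slope on gene length as covariate, which went from 0.037 ± 0.024 in controls to -0.038 ± 0.033 at this dose. The mean log2 fold change of the ribosomal protein list then went from 0.313 to 0.064, that of the mitochondrially encoded list from 0.412 to 0.133 and that of the erythroid list from 0.826 to 0.633. For the 17 called erythroid genes the median went from 1.264 (median SE 0.285) to 0.824 (0.317). In the main fit 5779 genes were called at 5 µM, 2963 higher and 2816 lower, against 5545 within code-523, 0 within code-524 and 1 with lane as covariate. Embryos of this dose shared no lane with controls, so the lane fit links them only through other groups. Its median SE over genes was 0.155 in place of 0.102. For the genes called in the main fit the median absolute log2 fold change was 0.159 in place of 0.319. Calls were thus lost with smaller values and a wider error.

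At 15 µM 5HPP-33 Cyp1a1 was the single gene called. It fell from 6.19 ± 2.86 to 2.38 ± 0.98 CPM (log2 -1.38, adjusted p = 0.0303), was -1.29 and not called with lane, and was not called without embryo Control_524_1B (-1.39). Cdkn1a (5.84 ± 1.62 CPM, 0.05) and Ccng1 (49.0 ± 10.1 CPM, 0.29) did not pass, and the p53 list was not called (camera, adjusted p = 0.924). Tubulin genes shifted downward as a list with 0 members called, or 2 of 10 over the list alone (camera, adjusted p = 0.000771; adjusted p = 0.457 with an estimated correlation), a call that was lost with lane as covariate. Tubb5 was -0.29 (adjusted p = 0.166). Mitochondrially encoded genes shifted upward with 6 of 13 over the list alone (adjusted p = 1.27e-06; adjusted p = 0.661 with an estimated correlation), as did ribosomal protein genes (adjusted p = 0.000424; adjusted p = 0.927 with an estimated correlation). The endoplasmic reticulum chaperone list shifted upward with 1 member over the list alone (adjusted p = 0.0232; adjusted p = 0.866 with an estimated correlation), and not without embryo Control_524_1B, when its mean went from 0.088 to 0.040. Neural crest (adjusted p = 0.00107; adjusted p = 0.616 with an estimated correlation), neural progenitor (adjusted p = 0.00131; adjusted p = 0.866 with an estimated correlation) and endothelial lists (adjusted p = 0.00583; adjusted p = 0.866 with an estimated correlation) shifted downward without a called member. Within code-523 4565 genes were called and within code-524 0, DESeq2 called 55, and without treated embryo HPP_15_524_11B 407 genes were called.

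Across control and the 3 doses of 5HPP-33 the largest rises per step were Alox5 (1.10), Tap1 (0.98), Ptprv (0.92) and Cdkn1a (0.91), and among the largest falls were Cyp1a1 (-0.52; -0.50 with lane), Nepn (-0.36) and Hes5 (-0.32). These slopes do not show a change at every step either. Cdkn1a was near the control level at 5 and 15 µM and rose at 30 µM (2.96). The trend called 795 genes, or 181 with lane as covariate. Where the libraries of 2 groups shared a lane, 5 and 15 µM 5HPP-33 did not differ in any gene (lane 2, 4 embryos each, edgeR quasi-likelihood, 774 genes at an unadjusted p under 0.05). TNP-470 at 25 µM differed from 5 µM 5HPP-33 in 268 genes (lanes 2 and 4, 8 embryos each), 17 p53 targets among the 195 that were higher with TNP-470. In lane 5, 30 µM 5HPP-33 differed from 15 µM in 25 genes, all higher at 30 µM and 8 of them p53 targets.

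**Figure D2:**
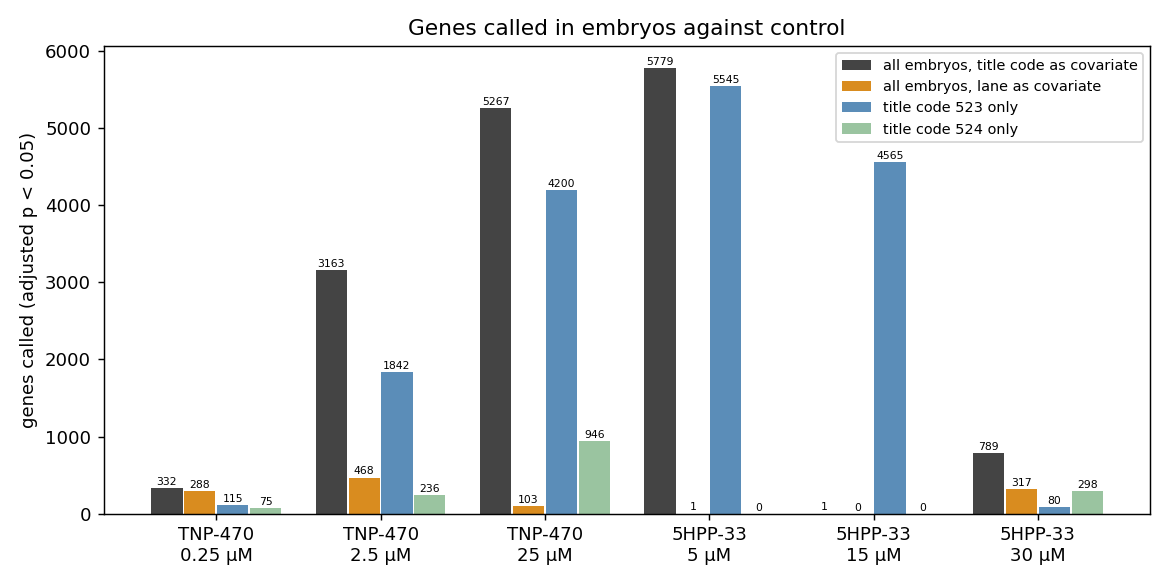
Number of genes called in embryos at each dose in 4 fits: all embryos with title code as covariate, all embryos with lane as covariate, and code-523 or code-524 alone; each bar is a count of genes. Counts of 5267 at 25 µM TNP-470 and 5779 at 5 µM 5HPP-33 went to 103 and 1 with lane as covariate, and 332 at 0.25 µM TNP-470 went to 288.

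Side by side at their top doses, which differ (25 and 30 µM), both compounds raised many of the same genes. Higher with both were Svop (4.72 with TNP-470, 3.82 with 5HPP-33), the costimulatory gene Cd80 (4.69, 4.38), Eda2r (4.07, 2.51), Fas (3.68, 2.74), Alox5 (3.64, 3.58), Ccng1 (3.60, 2.22), Cdkn1a (3.42, 2.96), Abcb1b (3.31, 2.70), the cytokine gene Lif (3.31, 2.95), Ptprv (3.24, 3.07), Phlda3 (2.93, 2.39) and Tap1 (2.78, 3.25). In all 153 genes were higher with both, 15 of them p53 targets, where 91.2 were expected by chance. Lower with both were 52, against 58.1 expected, and 42 went opposite ways. As both compounds were compared with the same controls, the controls were also divided, embryos A for TNP-470 and embryos B for 5HPP-33. Embryos A and B are of the same title numbers, so what a title number shares could still enter both sides. Then 75 genes were higher with both (9.655 expected) and 2 lower, and the correlation of log2 fold changes over genes was 0.274 in place of 0.440. Simulated unchanged groups against shared controls gave a mean correlation of 0.506 and 0 shared calls. They called at most 1 gene in each direction, so the 0 shared calls give no baseline for the shared counts. The simulation drew genes independently and held no differences between lanes. Lane as covariate left 61 genes higher with both (1.466 expected), 59 of them among the 153.

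Tested directly in the main fit, TNP-470 at 25 µM gave the larger p53 response than 5HPP-33 at 30 µM. Embryos of these groups shared no lane. Eda2r was higher with TNP-470 by 1.56 in log2, Ccng1 by 1.38, Fas by 0.95, Aen by 0.94, Tp53inp1 by 0.71, Zmat3 by 0.70, Phlda3 by 0.54, Cdkn1a by 0.46 and Mdm2 by 0.36. Btg2 (-0.34), Fdxr (-0.21), Perp (-0.59) and Ptp4a3 (-0.39) were lower. Of the 28 targets 15 were higher and 4 lower (camera, unadjusted p = 4.6e-07, and p = 0.00287 with an estimated correlation). The list was not tested with lane as covariate in this comparison. Ano3 (6.42 ± 2.30 against 1.47 ± 0.543 CPM, 2.13) and Nepn (1.40) were higher with TNP-470, and the gap junction gene Gjb2 (-1.76), the phosphate transporter gene Slc34a2 (-1.88) and Ybx1 (-1.75; -1.09 with lane) were lower. Of 2 identifiers named Map3k7, ENSRNOG00000047516 differed by -8.21, with counts that varied widely between 5HPP-33 embryos (0.0121 ± 0.0342 against 6.38 ± 13.9 CPM). The direct test called 5852 genes, 2769 of them higher with TNP-470, and 92 with lane as covariate, where Eda2r was 1.42 and Ccng1 1.26.

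In yolk sac pools no gene passed the edgeR test with title code as covariate at any dose when all pools were in the fit. The p53 targets rose less there than in the embryo. Cdkn1a went from 7.06 ± 5.77 to 8.48 ± 1.77 CPM at 25 µM TNP-470 (log2 0.32, 95% interval -0.35 to 0.99; n = 4 pools per group) and to 6.44 ± 2.93 CPM at 30 µM 5HPP-33 (-0.10, -0.79 to 0.59). Without control pool Control_524_1, at 15.7 CPM, these values were 0.97 (0.40 to 1.54) and 0.56 (-0.03 to 1.15), not called. Ccng1 went from 86.2 ± 37.8 to 113 ± 5.31 CPM with TNP-470 (0.40, 0.06 to 0.74) and to 72.6 ± 6.07 CPM with 5HPP-33 (-0.24). Without that pool Ccng1 was called at the 3 TNP-470 doses (0.83, 0.65 and 0.74; adjusted p = 0.000403, 0.0177 and 0.00258) and was 0.10 with 5HPP-33, and Aen was called at 0.25 µM TNP-470 (0.54, adjusted p = 0.0489). Eda2r (2.58, 1.52 to 3.64) stood highest at 25 µM TNP-470 and Gtse1, a p53 regulator in mitosis, was 0.51 (0.26 to 0.76), neither called. Among targets higher in embryos the median log2 fold change was 1.40 in embryos and 0.43 in yolk sacs at 0.25 µM TNP-470, 1.40 and 0.17 at 2.5 µM, 1.3 and 0.23 at 25 µM, and 0.86 and -0.07 at 30 µM 5HPP-33. Without that pool the yolk sac medians were 0.47, 0.34, 0.38 and 0.08. The p53 list shifted upward at 0.25 µM TNP-470 (camera, adjusted p = 0.00981; adjusted p = 0.72 with an estimated correlation), with 6 members higher and 3 lower over the list alone. It was not called at 2.5 µM (adjusted p = 0.144) or 25 µM (adjusted p = 0.0862). Without pool Control_524_1, which held high trophoblast and stress genes, its means went from 0.011 to 0.314, from -0.084 to 0.217 and from -0.066 to 0.235, and the list was called higher at all 3 doses (adjusted p = 2.06e-10, 1.31e-08 and 1.81e-08; adjusted p = 0.0171, 0.0206 and 0.0206 with an estimated correlation). At 5 and 15 µM 5HPP-33 it shifted downward (adjusted p = 0.0016 and 0.00107; adjusted p = 0.596 with an estimated correlation at both), which was lost without that pool.

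**Figure D3:**
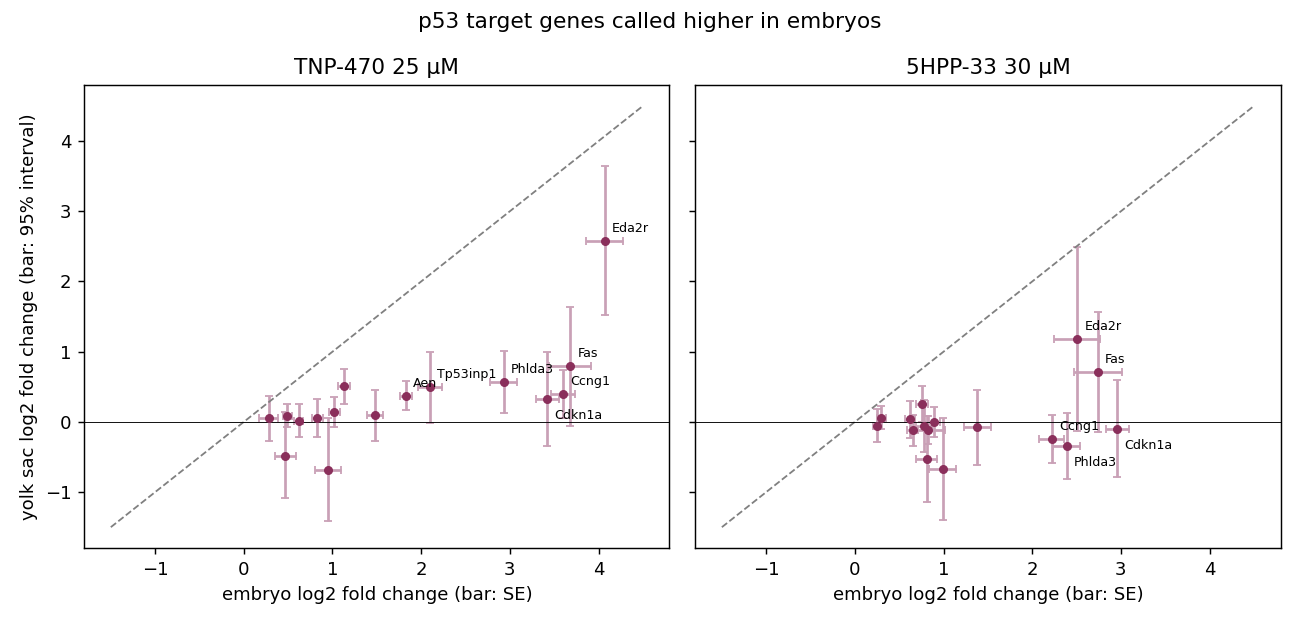
Log2 fold change of p53 targets called higher in embryos, embryo value on the horizontal axis (bars SE) and yolk sac value on the vertical axis (bars 95% interval), for 25 µM TNP-470 and 30 µM 5HPP-33; the dashed line marks equal values. Yolk sac intervals lay below the embryo value for 15 of 16 targets with TNP-470 and for 16 of 16 with 5HPP-33, or for 14 and 15 without control pool Control_524_1.

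In yolk sacs lists were called where no single gene was. ATF4 targets shifted downward at every dose. Among them were Slc7a1 (59.8 ± 86.0 to 7.90 ± 2.43 CPM, -2.76) and Slc7a5 (66.3 ± 67.5 to 18.5 ± 1.79 CPM, -1.78) at 25 µM TNP-470, neither called. At that dose 14 of 24 were lower over the list alone (camera, adjusted p = 8.57e-16; adjusted p = 0.148 with an estimated correlation). Pool Control_524_1 was the high library. Without it the list mean at that dose went from -0.921 to -0.383, and the calls held at the 3 TNP-470 doses (adjusted p = 0.69, 0.538 and 0.102 with an estimated correlation) and were lost at the 3 doses of 5HPP-33. Immediate early genes such as Fosl1 (26.3 ± 49.0 to 2.28 ± 0.483 CPM) and Ier3 (28.6 ± 43.5 to 6.61 ± 1.95 CPM) shifted downward at every dose (at 25 µM TNP-470 adjusted p = 1.79e-07; adjusted p = 0.661 with an estimated correlation). Without that pool the mean there went from -0.986 to -0.037 and the call was lost. Mitosis genes shifted upward at every dose, with Prc1 (0.24), Dlgap5 (0.27) and Kif2c (0.22) at 25 µM TNP-470, where 5 of 28 were higher over the list alone (adjusted p = 3.34e-19; adjusted p = 0.0549 with an estimated correlation). That call held without pool Control_524_1 at the TNP-470 doses, with a mean of 0.149 in place of 0.193 at 25 µM (adjusted p = 0.0505 with an estimated correlation). Visceral endoderm genes shifted upward at 25 µM TNP-470 (adjusted p = 4.93e-07; adjusted p = 0.764 with an estimated correlation) and not without pool Control_524_1. Retinoic acid targets shifted upward at 30 µM 5HPP-33 (adjusted p = 0.000563; adjusted p = 0.457 with an estimated correlation), which was lost without treated pool HPP_30_524_14 (adjusted p = 0.178), and leukocyte markers at 5 µM (adjusted p = 0.00754; adjusted p = 0.616 with an estimated correlation). Kdr (0.15), Flt1 (0.00), Vegfa (-0.03) and Tubb5 (-0.23) did not pass at 25 µM TNP-470.

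Beside the 0 genes called by edgeR quasi-likelihood, 910, 1473 and 1105 of 13480 genes had an unadjusted p under 0.05 at 0.25, 2.5 and 25 µM TNP-470 and 918, 740 and 865 at 5, 15 and 30 µM 5HPP-33. DESeq2 called 13, 72 and 83 at the TNP-470 doses and 34, 0 and 56 at the 5HPP-33 doses, against 0 by edgeR. The trends (977 and 651 unadjusted; DESeq2 75 and 3) and the direct comparison (546 unadjusted; DESeq2 8) called 0 genes by edgeR as well. Lane as covariate gave 0, 21 and 3 genes at the 3 TNP-470 doses and 17 in its trend. Leaving out pool Control_524_1 gave 2, 1 and 1 genes at the TNP-470 doses. When pool Control_524_2 was left out, the only code-524 control left was Control_524_1, which held high trophoblast and stress genes. That fit gave 33, 167 and 165 genes at the TNP-470 doses, 109 in the TNP-470 trend, and 93, 5 and 116 at the 5HPP-33 doses. Most of these were lower, as were most by DESeq2 (157 of 167 and 61 of 72 at 2.5 µM TNP-470; 112 of 116 and 52 of 56 at 30 µM 5HPP-33).

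The response of the p53 targets differed between the tissues. At 25 µM TNP-470 16 of the 28 responded less in yolk sac, among them Cdkn1a, Ccng1, Fas, Mdm2 and Zmat3 (camera over the list, p = 1.85e-11 with an estimated correlation), and at 30 µM 5HPP-33 13 did (camera, p = 5.99e-10 with an estimated correlation). Without the 2 yolk sac pools high in trophoblast markers, Control_524_1 and HPP_15_524_11, 12 and 7 remained. The largest differences were of another kind. Trophoblast genes such as the steroid enzyme genes Cyp11a1 (-10.76 at 25 µM TNP-470 and -9.62 at 30 µM 5HPP-33) and Hsd3b1 (-9.80, -9.36), Krt7 (-8.24, -8.55), Rhox9 (-8.87 with TNP-470) and Tfap2c (-8.61 with 5HPP-33) had such differences. They were at 569, 747, 675, 130 and 255 CPM in pool Control_524_1 and below 1 CPM in the other 3 control pools. The mesoderm and neural genes Olig2 (7.43), Foxb1 (6.89), T (6.24) and Meox1 (5.46) differed at 30 µM 5HPP-33 through 1 treated pool, HPP_30_524_14, in which T was at 23.0 CPM. T was at 0 in the other 3 pools. Differences of the other sign at 25 µM TNP-470 were those of Esm1, an endothelial gene (1.32), Ptgs1 (1.32), Gfpt2 (0.79) and Tmcc2 (0.78). These were lower in embryos (-0.865, -0.529, -0.379 and -0.431, Ptgs1 not called), while their yolk sac values of 0.461, 0.784, 0.407 and 0.332 were not called.

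In all 247 genes responded differently at 25 µM TNP-470, 225 of them lower in yolk sac, and 352 at 30 µM 5HPP-33, 276 of them lower; DESeq2 called 326 and 449. With embryos A and B summed and the title number, which pools and embryos share, as block the counts were 44 and 37. Without pool Control_524_1 the counts were 43 and 19, and without Control_524_2 they were 747 and 645. In the latter fit Control_524_1 was the only yolk sac control left of code-524. For TNP-470 the count was 602 without Control_523_2, 109 without treated pool TNP_25_524_7 and 118 without TNP_25_524_8. For 5HPP-33 it was 566 without Control_523_1 and 168 without treated pool HPP_30_524_14.

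In control cultures the tissues differed in 11286 of 14881 genes, 5907 of them higher in yolk sac. The primitive streak gene T was at 37.1 ± 11.2 CPM in embryos and 0.0543 ± 0.0632 CPM in yolk sacs (-12.44), and Foxb1 (9.89 ± 1.98 CPM), Fez1 (22.3 ± 2.90 CPM) and Cdx4 (35.5 ± 12.2 CPM) of embryos were at 0 in yolk sac controls. The sodium transporter gene Slc9a3 was higher in yolk sac (0.0205 against 9.33 ± 5.29 CPM, 10.03), as was Mageb4 (9.16). The fit had title code as covariate within each tissue, so this test and its log2 values hold at the level of code-523. These values are not the ratios of the printed means. With levels near the floor in the lower tissue they are not exact folds. The placental hormone gene Prl3d2 (2200 ± 4400 CPM) and the steroid enzyme gene Cyp17a1 (49.9 ± 98.8 CPM) were at 0 in embryos, and their yolk sac means rested on pool Control_524_1 (8810 and 198 CPM, against at most 1.28 and 0.642 CPM in the other 3 control pools).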

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

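Chosen after the results were seen were the gene-length covariate for the 5 µM 5HPP-33 embryos, the tests of the yolk sac result and the lane test of the p53 targets. The other tests were written before they were run.

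Embryos at 5 µM 5HPP-33 differed from control in 5779 genes and those at 15 µM in 1. A difference between sequencing lanes may account for this: the code-523 embryos of both doses lay in lane 2, and there the doses differed in 0 genes. A gene-length bias that differs between libraries may be part of it. With each library's slope on gene length as covariate 1 gene was called at 5 µM, as the median log2 fold change of the called genes, in their direction, went from 0.319 (median SE 0.086) to 0.140 (0.080). The erythroid list kept more, with a mean of 0.633 in place of 0.826. The slope was computed from the same expression values and followed the groups (0.005 to 0.069 in controls, -0.089 to -0.001 at 5 µM). As covariate it could therefore also remove a compound effect, so this fit cannot tell a bias from a response. A compound effect that grows with dose could not be told apart when each dose had its own control embryos. Against control embryos A alone 3593 genes were called at 5 µM. Of these 56.1% had the same sign at 30 µM against control embryos B. By that measure 96% had the same sign at 15 µM and 97.7% at 25 µM TNP-470, whose code-523 embryos shared the lane. Control embryos A and B are of the same title numbers, so what a title number shares could still enter both sides.

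In yolk sacs edgeR with title code as covariate called no gene at any dose with all pools in the fit. Lane as covariate gave 21 and 3 genes at 2.5 and 25 µM TNP-470, and DESeq2 called genes as well. A control pool with trophoblast transcripts could have hidden a wide response, but without the pools high in those markers at most 1 gene was called at any dose. It did mask a rise of Ccng1, which was called at every TNP-470 dose without pool Control_524_1 (0.74 in place of 0.40 at 25 µM). Aen was called at 0.25 µM without that pool (edgeR quasi-likelihood, adjusted p = 0.0489), although its value changed little (0.54 in place of 0.43). Fewer libraries per group could have hidden a p53 response as large as in embryos, yet for at least 14 of 16 targets higher in embryos at 25 µM TNP-470 the yolk sac 95% interval lay below the embryo value, with all pools (15) or without that pool (14). These targets were picked by their embryo values, which were taken as exact, and that favours this outcome. The test of the difference itself over all 28 targets called 16 lower in yolk sac at that dose. It called 12 without the pools high in trophoblast markers. A response that is smaller in the yolk sac than in the embryo remains a possible explanation for these targets. Exposure of the tissue to compound was not measured.

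In embryos p53 targets were higher at every TNP-470 dose and at 30 µM 5HPP-33. Sequencing lane alone could not account for this. In lanes that held both groups, or with lane as covariate, at least 9 targets were called higher in each comparison. The 9 were at 30 µM 5HPP-33 in lane 3, where treated embryos were of code-523 and controls of code-524. That comparison cannot tell compound from title code, and lane as covariate over all embryos gave 15 there. Gene-length bias could not account for the rise either, as at least 15 were called with each library's slope on gene length as covariate. Nor could embryos high in visceral endoderm markers or low in heart markers, without which at least 14 were called. A response to each compound remains the likely source, and its upstream cause was not tested.

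Dixon's test singled out 5 of 74 sets of library values, where chance gives about 1 in 20, or 3.7. Embryo HPP_5_524_9B had the lowest total count of its group, 8.71 M expected counts. In embryo Control_524_1B Slc7a3 was at 111 CPM and Stc2 at 23.3 CPM, far above the other controls, and Svop was at 0 CPM. Chrna7 was at 1.78 CPM in embryo HPP_30_523_14A, the lowest of its group.

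The response differed between the tissues in 247 genes at 25 µM TNP-470 and in 352 at 30 µM 5HPP-33, by a test of the difference itself, or in 44 and 37 with embryos summed and the title number as block. Without pool Control_524_1 the counts were 43 and 19. With TNP-470 the log2 differences, yolk sac minus embryo, were -10.76 for Cyp11a1, -9.80 for Hsd3b1, -8.87 for Rhox9, -8.24 for Krt7, 1.32 for Esm1, 1.32 for Ptgs1, 0.79 for Gfpt2 and 0.78 for Tmcc2. With 5HPP-33 they were -9.62 for Cyp11a1, -9.36 for Hsd3b1, -8.61 for Tfap2c, -8.55 for Krt7, 7.43 for Olig2, 6.89 for Foxb1, 6.24 for T and 5.46 for Meox1. Those of Cyp11a1, Hsd3b1, Rhox9, Krt7 and Tfap2c rested on control pool Control_524_1. Those of Olig2, Foxb1, T and Meox1 rested on treated pool HPP_30_524_14.

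The libraries of each comparison were also divided in other ways, as a check of whether chance can be excluded. Among 40 splits of the embryos 1, the real one, called as many genes at 0.25 µM TNP-470 (332; highest other 1), 2.5 µM (3163; 19), 25 µM (5267; 2), in the TNP-470 trend (5702; 0), at 5 µM 5HPP-33 (5779; 6) and in the direct comparison (5852; 436). These splits do not exclude a lane effect, which follows the real groups. At 15 µM 5HPP-33 7 of 40 splits called as many (1; 33), at 30 µM 2 of 40 (789; 794) and in the 5HPP-33 trend 3 of 40 (795; 2071), so chance cannot be excluded for these counts. In yolk sacs, where the real counts were 0, all 35 splits of each dose comparison called as many, with highest other counts of 207, 108 and 83 for TNP-470 and 195, 708 and 80 for 5HPP-33 in order of dose. So did all 40 splits of the trends (highest other 1 and 2494) and all 35 of the direct comparison (highest 0). For the tissue difference in response 5 of 25 splits called as many for TNP-470 (247, highest other 369) and 5 of 25 for 5HPP-33 (352, highest other 570). Chance cannot be excluded for these counts either. For the control tissues 1 of 25 splits called as many (11286, highest other 8390). With real counts of 0 the yolk sac splits could not have come out otherwise, so the share of splits tests nothing there. Other splits that called several times the real count, as at 15 µM 5HPP-33 and in the 5HPP-33 trend of embryos, and yolk sac splits that called up to 708 genes at a dose and 2494 in the 5HPP-33 trend, point to a structure of the samples beside the groups.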

How the results depend on the processing

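Chosen after the data were seen were the gene-length covariate, leaving out the embryos with unusual markers, embryo A or B alone, lanes holding both groups, quality weights, the yolk sac fits without the trophoblast-high pools, the pairing permutations, the fits without single embryos and the shared responses with lane. All other alternatives were planned. The cause of the changes below was not tested, except that single codes, letters, lanes or groups hold fewer samples.

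Numbers of genes called that differed by more than 1.5 times from the main fit follow. At 0.25 µM TNP-470 (332) they were 115 in code-523, 75 in code-524, 179 with embryos A and B summed, 220 with the gene-length covariate, 70 with embryo A and 63 with embryo B. At 2.5 µM (3163) they were 468 with lane, 1842 in code-523, 236 in code-524, 1870 summed, 1187 with gene length, 4816 without the embryos with unusual markers, 151 with embryo A, 271 with embryo B and 1152 in lanes holding both groups. At 25 µM (5267) they were 103 with lane, 946 in code-524, 708 with gene length, 914 with embryo A and 1602 with embryo B. In the TNP-470 trend (5702) they were 99 with lane, 1356 in code-524, 1342 with gene length, 844 with embryo A and 2930 with embryo B.

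At 5 µM 5HPP-33 (5779) the counts were 1 with lane, 0 in code-524, 1 with gene length, 2874 with embryo A and 1 with embryo B. At 15 µM (1) they were 55 by DESeq2, 4565 in code-523, 84 with gene length and 352 without the embryos with unusual markers. They were 0 there with no filter, lane, the compared groups alone, code-524, summed embryos, title number as random block, embryo A and embryo B. At 30 µM (789) they were 317 with lane, 121 with the compared groups alone, 80 in code-523, 298 in code-524, 514 summed, 475 with the random block, 97 without the embryos with unusual markers, 50 with embryo A, 59 with embryo B and 29 in the lane holding both groups. In that lane the treated embryos were all of code-523 and the controls all of code-524. In the 5HPP-33 trend (795) they were 181 with lane, 235 with the groups alone, 63 in code-523, 396 summed, 505 with the random block, 1324 with gene length, 106 without the embryos with unusual markers, 52 with embryo A and 63 with embryo B. In the direct comparison (5852) they were 92 with lane, 2456 in code-524, 2800 with embryo A and 2446 with embryo B.

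In yolk sacs the main counts were 0. DESeq2 called 13, 72 and 83 genes at the 3 TNP-470 doses, 75 in its trend, 34 and 56 at 5 and 30 µM 5HPP-33, 3 in its trend and 8 in the direct comparison. Lane gave 21 and 3 at 2.5 and 25 µM TNP-470 and 17 in the trend. Quality weights gave 4, 7 and 7 at the TNP-470 doses, 3 in the trend and 8 in the direct comparison, which also gave 2 with the groups alone. Without the trophoblast-high pools 1 gene was called at each TNP-470 dose, in its trend and in the direct comparison.

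The tissue difference in response went from 247 to 44 genes for TNP-470 and from 352 to 37 for 5HPP-33 with embryos summed and the title number as block, and to 39 and 25 without the trophoblast-high pools. DESeq2 divided the calls otherwise, 80 higher and 246 lower against 22 and 225 for TNP-470, and 155 and 294 against 76 and 276 for 5HPP-33. List calls went from 108 to 4 with an estimated correlation. Shared embryo responses went from 205 to 77 with divided controls and 61 with lane, and shared yolk sac responses from 0 to 41 with DESeq2. Among 3198 named gene values under other settings 2 called values changed sign, both with lane: Nkd1 at 25 µM TNP-470 (0.04) and Stc2 at 5 µM 5HPP-33 (0.30). A further 46 that were called in neither fit changed sign.

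Leaving out embryo Control_524_1B gave 223, 2453 and 4765 genes at the TNP-470 doses, 5280 in the trend, 5328 at 5 µM 5HPP-33 and 516 at 30 µM. At 15 µM it gave 0 and in the 5HPP-33 trend 571, and leaving out embryo HPP_15_524_11B gave 407 and 851. No other embryo was left out alone for these counts. Leaving out each yolk sac pool in turn gave 0 to 33, 0 to 167, 0 to 165 and in the trend 0 to 109 for TNP-470, and 0 to 93, 0 to 5, 0 to 116 and 0 to 2 for 5HPP-33, with 0 to 0 in the direct comparison. For the tissue difference it gave 43 to 747 for TNP-470, 19 to 645 for 5HPP-33 and 10899 to 11211 in controls.

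Yolk sac pools resembled the embryos of their own title number weakly. Over 28 title numbers the median correlation of their residuals was 0.0933 (-0.0993 to 0.199) and 13 were above 0.1. For 19 title numbers the own pool correlated best with the embryos, where 7 were expected by chance (permutation within groups, p = 0.0001; within groups and title codes 24 against 14, p = 0.0058). The fits that treat pools and embryos as separate leave this out. Embryos A and B had a median of -0.1235, and 1 title number was above 0.1. Residuals were deviations from the group mean, which makes the correlation between unrelated embryos of a group negative. That median therefore does not show embryos A and B to be unlike. RLE factors and leaving out the title code kept every embryo count within 1.5 times, and the control tissue count kept within it under every alternative, from 10593 with lane to 11953 with no filter. In yolk sacs, with 4 libraries per group against 8, the simulated test recovered 52.2% of genes changed 1.5 fold, against 85.1% in embryos.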

Other observations

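The test below was chosen after the values were seen.

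Embryos differed in the levels of marker genes of some tissues. Whether this reflects the amount of tissue or expression of the markers was not tested. Heart muscle genes were lowest, as mean log2 deviation, in embryos TNP_25_523_3A (0.25 µM, -3.54), HPP_5_523_10A (-3.49), Control_523_2A (-1.96), HPP_30_523_14B (-1.95), TNP_25_523_7A (25 µM, -1.66), Control_524_2B (-1.26) and HPP_5_523_9A (-1.19). Visceral endoderm genes were highest in embryos HPP_30_524_13A (3.83), TNP_25_524_8B (25 µM, 2.92), HPP_5_524_10A (2.56), HPP_30_524_14B (2.22), HPP_30_523_14A (1.95) and TNP_25_523_4A (0.25 µM, 1.85), and in both embryos of title number 3 of code-524 (0.25 µM TNP-470, 1.52 and 1.62). Among yolk sac pools trophoblast and decidua genes were highest in Control_524_1 (2.45) and HPP_15_524_11 (1.57).

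The doses at which Cdkn1a rose differed between the compounds. With TNP-470 its level was 56.5, 63.5 and 60.4 CPM over doses 100 times apart, and with 5HPP-33 it was 5.10 and 5.84 CPM at 5 and 15 µM and 43.8 CPM at 30 µM.

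A hypothesis was that stress transcripts of a title number come from a shared culture or dissection. Over 28 title numbers the mean of the ATF4 targets in the yolk sac pool, taken within group, correlated with that of its embryos (r = 0.688, permutation p = 0.0014; Spearman 0.518, permutation p = 0.00497). Without title numbers 11 and 1 of code-524, the farthest from the rest, r was 0.536. The values may reflect a shared handling of the conceptuses, and what that was is not given in the sources used here.

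The slope of each library on gene length, in log2 per doubling of length, was 0.037 ± 0.024 in control embryos and differed at 0.25 µM TNP-470 (-0.003 ± 0.023), 2.5 µM (-0.006 ± 0.018), 25 µM (-0.034 ± 0.020) and 5 µM 5HPP-33 (-0.038 ± 0.033), with exact permutation p adjusted to 0.00374, 0.00124, 0.000465 and 0.000465. At 15 µM 5HPP-33 it was -0.011 in lane 2 and 0.069 in lane 5. Group means also varied within a lane, which was not tested. Control and 0.25 µM TNP-470 were at 0.035 ± 0.021 and 0.006 ± 0.005 in lane 1 and at 0.032 ± 0.029 and -0.012 ± 0.031 in lane 3. In lane 5 30 µM 5HPP-33 was at 0.019 ± 0.083.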
